A study of Schizosaccharomyces pombe with 21 samples.

How the data were processed

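RNA-seq of polyA RNA was analysed from 21 libraries of fission yeast strain AGP72. Per the labels, RNA was extracted with hot acid phenol and libraries were made with the Illumina TruSeq stranded mRNA kit and sequenced in paired-end mode on a NovaSeq. The 7 groups are phosphate-replete cells at 0 h and cells starved of phosphate for 2, 4 and 8 h without and with cycloheximide, with 3 libraries each, which the labels call biological replicates. Groups were taken from the sample titles and treatments.

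The authors deposited a table of read counts per gene for 6988 genes and the 21 libraries, and 6 tables that compare each starved group with 0 h. HISAT2 2.1.0, SAMtools, HTSeq 0.10.0, DESeq, DESeq2 and the genome build ASM294v2 are named in the submitters' processing notes. The roles and settings of these tools, the strand setting of the counting included, are not given in the sources used here. The counts deposited by the authors are whole numbers that are not normalized, with totals from 22079413 to 33563867 per library. The authors' comparison tables give a log2 fold change per gene and an adjusted p-value, from DESeq2 per the file headers. They also give a signal per group, the authors' group mean of counts divided by size factors, per the file headers and the values. These tables were set beside the results computed here as a description and entered no test. Each gene's symbol and product were taken from them, which gave 4987 genes a symbol, and other genes keep their systematic identifier. The reference at hand is of another build (ASM294v3), so it was used only for older symbols and for which genes neighbour each other, and no coordinates are given.

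Genes were tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood test on the deposited counts, TMM scaling and the default filter on low counts, which removed 596 genes and left 6392. These were 5056 protein-coding genes, 1225 noncoding RNA genes, 44 small nuclear and nucleolar RNA genes, 38 tRNA genes and 29 rRNA genes. Of 187 tRNA genes in the table, only these 38 were tested. The filter asks for enough counts in as many libraries as a group holds, so a gene can pass through a single group. The listed mitochondrial genes had no counts and were not analysed here. All libraries entered 1 fit with the group as its term, which gave 7.07 prior degrees of freedom, and 12 comparisons were drawn from it. A gene is called at a Benjamini-Hochberg adjusted p below 0.05 and a change of at least 2-fold, and "higher", "lower", "rose" and "fell" refer to this call. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes. A fold against a group without counts depends on the prior count, so list medians are also given with such genes at their bound, with a floor of 3 counts over the group. Before the data were examined, the groups, tests, thresholds, 36 gene lists, the rule for named genes and all alternatives were fixed. The rule for named genes took, per comparison, the 6 highest and 6 lowest log2 fold changes among called genes with a symbol, a mean of at least 100 scaled counts in the higher group and no overlap between the libraries of both groups (a condition not applied to the interaction of drug and time). It added up to 4 called members per list with the largest changes (2 per direction where members went both ways), and always pho1, pho84, tgp1, maf1, pho7, csk1 and SPNCRNA.1343.

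Lists with at least 5 tested members, 35 in all, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Shares of counts by class of RNA were compared between drug and no drug with a two-sided exact permutation test within times, adjusted over 6 classes. The overlap of comparisons that share the 0 h libraries was set beside 20 simulations of unchanged groups against those libraries. The simulated groups were drawn from the mean of those same libraries.

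The gene test was tested on simulated data for 8 h against 0 h, drawn from the means and library sizes of the 6392 genes. Changes were set only in genes above a minimum expected count, so the shares found do not cover genes with few counts. Of 50 genes changed by 1.5-fold, 45 had an adjusted p below 0.05, all 50 changed by 2.5-fold, 4-fold and 8-fold each were called, and 1 of 6192 unchanged genes was called. Replicate pairs differed by more than sampling noise, with a chi-square per gene of 3.66 to 23.6 over 21 pairs, so that no library was counted as a copy of another.

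The alternatives were the RLE size factors, library size alone, no filter and a stricter filter on low counts (a mean of at least 100 counts), DESeq2 1.42.0 with a Wald test, a fit with the compared groups only, the replicate number as a block, each library left out, any fold in the look-up, and class shares without the 10 most abundant genes. The measure is relative: a change in the total amount of RNA per cell does not show, and genes that take many counts lower the share of others. Genes with near-identical copies, such as those of ribosomal proteins, tRNAs, rRNAs, Tf2 retrotransposons and wtf elements, are uncertain where the counting could split reads between copies, and so are overlapping genes. Libraries were made from polyA RNA, so counts at tRNA, rRNA, small nuclear and nucleolar RNA genes cover only what was carried through that selection. Bounds from counts cover counting error only.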

Results

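Gene expression in fission yeast (Schizosaccharomyces pombe) was measured by RNA-seq of polyadenylated RNA during long-term phosphate starvation, with and without cycloheximide, an inhibitor of translation elongation. The 21 libraries came from strain AGP72, of mating type h-, and formed 7 groups of 3. They were phosphate-replete cells in log phase (0 h), cells starved for 2, 4 or 8 h, and cells starved for 2, 4 or 8 h with cycloheximide at 100 µg/ml. The title of the series places the work in the context of Maf1, the repressor of RNA polymerase III, of quiescence against death, and of faulty tRNA production. Total counts per library ranged from 23006377 to 31132468 at 0 h, 26874261 to 28718605 at 2 h, 27401709 to 33563867 at 4 h and 24249785 to 28684142 at 8 h. With cycloheximide the ranges were 22086821 to 32500458 at 2 h, 22611265 to 29290388 at 4 h and 22079413 to 31689948 at 8 h. The tested genes numbered 6392, of which 5056 were protein-coding and 1225 noncoding RNA genes. The first 3 principal components held 56.6%, 25.5% and 8.68% of the variance, and the scores of the starved libraries with and without drug on component 1 had opposite signs. The gene with the most counts, not corrected for length, was fba1 (fructose-bisphosphate aldolase) at 0 and 2 h, tdh1 (glyceraldehyde-3-phosphate dehydrogenase) at 4 h, and pho1 (secreted acid phosphatase) at 8 h, where it took 2.92% to 3.09% of all counts. With drug it was tef103, which encodes translation elongation factor EF-1 alpha. The 0 h cells grew in YES and the starved cells in ePMGT without phosphate, so each comparison with 0 h contains the change of medium as well as the loss of phosphate.

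The genes of phosphate uptake were higher after 2 h of starvation than at 0 h. Normalised counts (CPM) of tgp1 (SPBC1271.09), a glycerophosphodiester transporter, were 17.4 ± 0.873 at 0 h and 497 ± 35.8 at 2 h (mean ± SD, n = 3), a log2 fold change of 4.84 ± 0.07 (± SE, as for all log2 values that follow). Acid phosphatase gene pho1 (SPBP4G3.02) rose by 2.16 ± 0.08, the phosphate transporter gene pho84 (SPBC8E4.01c) by 1.60 ± 0.07 and the inositol pyrophosphate kinase gene asp1 by 1.10 ± 0.05. Of the 13 tested genes of phosphate acquisition and signalling, these 4 were called higher (median 0.66, camera adjusted p = 2.1e-04, adjusted p = 0.167 with an estimated correlation). The uracil-regulated genes urg1 (6.52 ± 0.12) and urg2 (5.47 ± 0.12), the heme transporter gene str3 (5.96 ± 0.21) and the amino acid permease gene isp5 (4.57 ± 0.09) were among the highest log2 fold changes with tgp1. Iron acquisition genes rose too, with 7 of 14 called higher (median 0.87, camera adjusted p = 1.1e-06, adjusted p = 0.167 with an estimated correlation). Among them were the ferric reductase gene frp1 (3.24 ± 0.15) and the iron uptake genes fio1 (2.83 ± 0.13) and fip1 (2.69 ± 0.09). ecl3, which encodes an extender of lifespan, rose by 3.53 ± 0.18. The proline transporter gene put4 rose by 2.36 ± 0.08 and the multidrug transporter gene bfr1 by 1.66 ± 0.10. Among ribosome biogenesis genes, 18 of 105 were called lower (median -0.73, camera adjusted p = 1.2e-29, adjusted p = 0.171 with an estimated correlation). Examples were kri1 (-1.22 ± 0.05), nop12 (-1.20 ± 0.05), rrp8 (-1.20 ± 0.05) and utp25 (-1.16 ± 0.04). Among the lowest values were those of pan5 (-1.69 ± 0.05), ptr2 (-1.48 ± 0.06), mis3 (-1.45 ± 0.06) and prt2 (-1.45 ± 0.09), the noncoding RNA transcribed upstream of pho84. In all, 252 genes were called higher and 116 lower. With scaling by library size alone the split was 294 higher and 76 lower, and with the stricter filter on low counts 77 were lower.

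At 4 h ribosomal protein genes had fallen and stress genes had risen. All 138 tested ribosomal protein genes were called lower, with a median log2 fold change of -2.65 (camera adjusted p = 8.5e-33, adjusted p = 0.270 with an estimated correlation). The acidic ribosomal protein gene rpp203 went from 567 ± 32.2 to 24.1 ± 3.25 CPM (mean ± SD, n = 3), a log2 change of -4.55 ± 0.08, and rpl1603 and rpl3002 changed by -4.42 ± 0.06 and -4.12 ± 0.07. Most of these genes have a near-identical copy with which reads can be shared. Ribosome biogenesis genes were lower in 83 of 105 cases (median -1.50, camera adjusted p = 1.5e-23, adjusted p = 0.270 with an estimated correlation). The helicase gene dbp3 had a change of -2.64 ± 0.06 and gar1 of -2.27 ± 0.05. Translation factor genes fell in 26 of 35 cases (median -1.17, camera adjusted p = 1.8e-11, adjusted p = 0.270 with an estimated correlation), tif1 among them (-2.06 ± 0.06). Amino acid biosynthesis genes fell in 23 of 48 cases (median -0.98, camera adjusted p = 2.4e-09, adjusted p = 0.270 with an estimated correlation), and the sulphate assimilation gene met14 had a change of -2.71 ± 0.04. The pyrimidine gene ura3 had a log2 change of -2.81 ± 0.06 and the adenine salvage gene apt1 had a change of -4.10 ± 0.06. Within the RNA polymerase I and III machinery, 19 of 36 genes were called lower and 1 higher (median -1.07, camera adjusted p = 4.4e-06, adjusted p = 0.270 with an estimated correlation). The 1 higher was maf1 (SPAC31G5.12c), at 23.9 ± 0.941 CPM at 0 h and 103 ± 3.75 CPM at 4 h, with a log2 fold change of 2.11 ± 0.06. By contrast sla1, the La protein gene, and the polymerase III subunit gene rpc11 had changes of -2.31 ± 0.05 and -2.08 ± 0.07. Core environmental stress genes rose in 26 of 36 cases (median 1.98, camera adjusted p = 6.4e-09, adjusted p = 0.270 with an estimated correlation). Examples were the metallothionein gene zym1 (5.12 ± 0.17), bit2 (5.09 ± 0.14), hsp9 (3.96 ± 0.12) and the small heat shock protein gene hsp16 (3.72 ± 0.27). Autophagy genes rose in 16 of 30 cases (median 1.09, camera adjusted p = 2.8e-09, adjusted p = 0.270 with an estimated correlation), atg20 by 2.08 ± 0.07 and atg4 by 2.04 ± 0.06. The gluconeogenic gene fbp1 rose by 4.16 ± 0.14, the glyceraldehyde-3-phosphate dehydrogenase gene gpd3 by 4.51 ± 0.12 and the pyruvate decarboxylase gene pdc201 by 4.29 ± 0.13. The phosphate list had 7 genes higher and 2 lower (median 1.18, camera adjusted p = 0.0193, adjusted p = 0.270 with an estimated correlation). Its higher genes included tgp1 (5.87 ± 0.07), pho1 (3.20 ± 0.09) and pho84 (2.02 ± 0.07). Its lower genes were the polyphosphatase gene ppx1 (-1.01 ± 0.04) and the kinase gene csk1 (SPAC1D4.06c, -1.01 ± 0.06), both near 2-fold and below it with RLE factors, library size alone, the stricter filter or DESeq2. The highest value among named genes was that of ddr48 (6.85 ± 0.26). In all, 906 genes were called higher and 889 lower, or 1154 and 670 with library size alone, which moves the median of all genes to 0.20.

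By 8 h pho1 had become the gene with the most counts and pheromone genes had risen. pho1 stood at 1591 ± 115 CPM at 0 h and 28693 ± 1832 CPM at 8 h (mean ± SD, n = 3), a log2 fold change of 4.17 ± 0.09, and tgp1 and pho84 reached 6.95 ± 0.08 and 2.58 ± 0.08. The phosphate list had 7 genes higher and 1 lower (median 1.31, camera adjusted p = 0.0192, adjusted p = 0.271 with an estimated correlation), the last being ppx1 (-1.07 ± 0.04), which was below 2-fold with library size alone. SPNCRNA.1343, the noncoding RNA upstream of tgp1, dropped from 48.1 ± 3.01 to 6.54 ± 0.669 CPM, a log2 change of -2.87 ± 0.08. The M-factor pheromone gene mfm1 rose by 7.67 ± 0.14. Of the 7 tested M-cell specific genes, 6 were called higher (median 3.13, camera adjusted p = 0.00148, adjusted p = 0.271 with an estimated correlation). They included mfm3 (5.52 ± 0.14) and the P-factor receptor gene mam2 (4.21 ± 0.15). Genes of sexual differentiation rose in 10 of 18 cases (median 1.11, camera adjusted p = 3.1e-04, adjusted p = 0.271 with an estimated correlation). The pheromone response kinase gene spk1 rose by 2.57 ± 0.10 and mei2, a regulator of meiosis, by 2.55 ± 0.07. Ribosomal protein genes were again all called lower (median -3.61, camera adjusted p = 1.0e-32, adjusted p = 0.271 with an estimated correlation). The lowest of them were rpp203 (-6.42 ± 0.09), rpl1002 (-5.61 ± 0.08) and rps1402 (-5.45 ± 0.09). Ribosome biogenesis genes were lower in 78 of 105 cases (median -1.43, camera adjusted p = 2.6e-19, adjusted p = 0.271 with an estimated correlation). Translation factor genes were lower in 27 of 35 (median -1.43, camera adjusted p = 5.2e-11, adjusted p = 0.277 with an estimated correlation). Amino acid biosynthesis genes were lower in 27 of 48 (median -1.10, camera adjusted p = 2.2e-09, adjusted p = 0.271 with an estimated correlation). RNA polymerase I and III genes split into 2 higher, maf1 (2.22 ± 0.06) and the TFIIIB subunit gene brf1 (1.24 ± 0.05), and 21 lower (median -1.06, camera adjusted p = 9.6e-05, adjusted p = 0.271 with an estimated correlation). The lower ones included sla1 (-2.49 ± 0.05) and nuc1 (-2.03 ± 0.05), the gene of the largest subunit of polymerase I. Core environmental stress genes rose in 24 of 36 cases (median 1.96, camera adjusted p = 1.2e-07, adjusted p = 0.271 with an estimated correlation), zym1 by 6.05 ± 0.18 and bit2 by 5.67 ± 0.13. Autophagy genes rose in 21 of 30 (median 1.31, camera adjusted p = 7.4e-10, adjusted p = 0.271 with an estimated correlation), atg4 by 2.47 ± 0.06 and the mitophagy receptor gene atg43 by 2.36 ± 0.05. Glucose-repressed and hexose transport genes rose in 11 of 23 cases (median 0.99, camera adjusted p = 1.5e-04, adjusted p = 0.271 with an estimated correlation), led by fbp1 (6.21 ± 0.14). The alpha-galactosidase gene mel1 rose by 7.17 ± 0.25. In all, 1212 genes were called higher and 997 lower, or 1458 and 782 with library size alone (median of all genes 0.19). pfd1-antisense-1 had the lowest value among named genes (-7.24 ± 0.22). The strand setting of the counting is not given in the sources used here, so antisense RNAs and the genes opposite them may share counts.

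**Figure D1:**
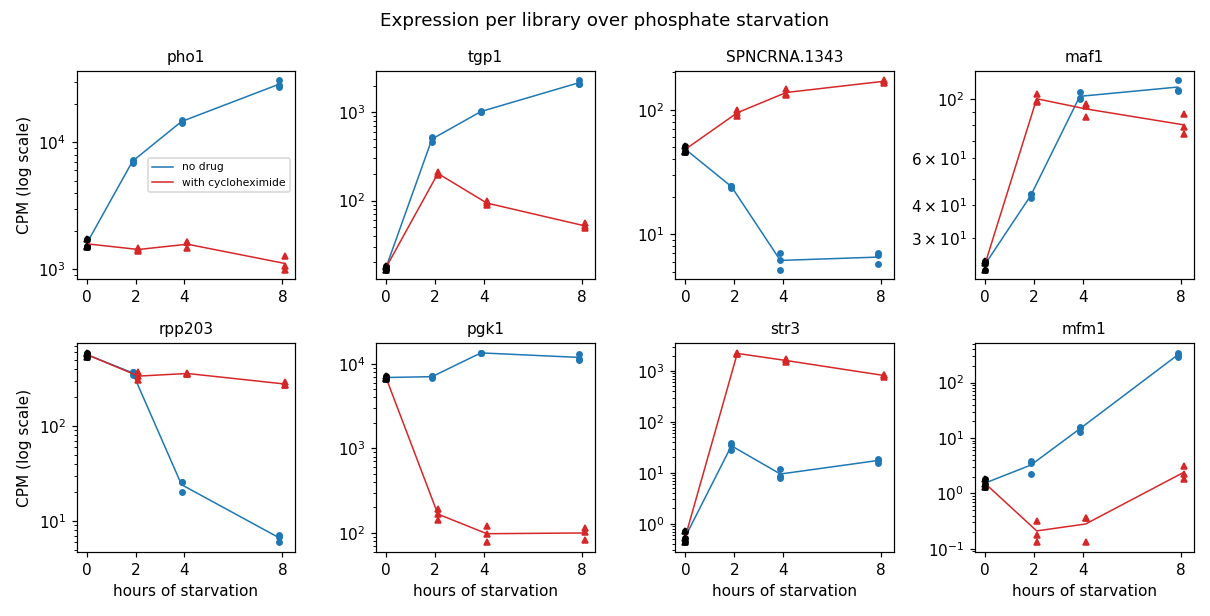
Normalised counts (CPM, log scale) against hours of starvation for 8 genes, with a point per library (blue circles without drug, red triangles with cycloheximide, black at 0 h) and lines through the means of 3 libraries. Without drug the mean of pho1 went from 1591 ± 115 to 28693 ± 1832 CPM (± SD) and with cycloheximide it was 1112 ± 152 CPM at 8 h.

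After 2 h of starvation with cycloheximide, iron and stress genes were higher and glycolytic and chaperone genes lower than at 0 h. The 0 h cells had no drug, so the comparisons of cycloheximide groups with 0 h contain the effect of the drug as well as those of starvation and medium. The heme transporter gene str3 went from 0.555 ± 0.153 to 2224 ± 65.9 CPM (mean ± SD, n = 3), a log2 fold change of 11.99 ± 0.17, and the potassium exporter gene cta3 from 2.20 ± 0.0246 to 4779.9 ± 203 CPM (11.08 ± 0.12). Iron acquisition genes were higher in 12 of 14 cases and lower in 1 (median 2.28, camera adjusted p = 1.2e-04, adjusted p = 0.232 with an estimated correlation). The heme uptake gene shu1 rose by 6.84 ± 0.30 and frp1 by 6.44 ± 0.14. The phosphoglycerate kinase gene pgk1 went from 6874 ± 288 to 167 ± 24.2 CPM (-5.36 ± 0.14), and eno101 (enolase) and tdh1 had changes of -4.60 ± 0.11 and -4.29 ± 0.12. Of 20 genes of glycolysis and fermentation 11 were called lower and 4 higher (median -1.46, camera adjusted p = 0.0115, adjusted p = 0.673 with an estimated correlation). The higher ones included pdc201 (4.39 ± 0.13) and the aldehyde dehydrogenase gene atd1 (3.38 ± 0.07). Heat shock chaperone genes fell in 13 of 21 cases (median -1.49, camera adjusted p = 1.3e-04, adjusted p = 0.499 with an estimated correlation), including ssa2 (-4.07 ± 0.12) and hsp90 (-3.27 ± 0.07). At 2 h without drug the medians were 0.08 for the glycolysis list and -0.30 for the chaperone list. Core environmental stress genes were higher in 24 cases and lower in 3 of 36 (median 1.57, camera adjusted p = 6.9e-05, adjusted p = 0.556 with an estimated correlation), with the transcription factor gene atf21 at 6.48 ± 0.23. Counts at tRNA genes were higher in 36 of 38 cases, with a median log2 fold change of 4.41, or 4.19 with the genes that had no count in a group at their bound (camera adjusted p = 6.4e-06, adjusted p = 0.00946 with an estimated correlation). Only 38 of 187 tRNA genes passed the filter. All tRNA genes together had a median of 78 counts per library at 0 h and 1499 at 2 h with drug. Genes could thus pass through the drug libraries, so the share called, the median and the list test depend in part on the filter. The same limit holds for the tRNA list in the comparisons below. Counts at small nuclear and nucleolar RNA genes were higher in 21 and lower in 3 of 44 cases (median 0.84, camera adjusted p = 0.00618, adjusted p = 0.353 with an estimated correlation). The higher ones included snu4 (3.35 ± 0.25) and snoU14 (3.20 ± 0.05). The phosphate list had 6 genes higher and 1 lower (median 0.45, camera adjusted p = 0.00445, adjusted p = 0.353 with an estimated correlation). tgp1 rose by 3.54 ± 0.07, pho84 by 1.06 ± 0.07, the SPX-domain ubiquitin ligase gene pqr1 by 2.09 ± 0.05 and pho7 (SPBC27B12.11c), which encodes a transcription factor of phosphate genes, by 1.59 ± 0.04. The log2 fold change of pho1 was -0.15 ± 0.08, and it was not called. maf1 rose by 2.08 ± 0.06, to 101 ± 4.02 CPM, and brf1 by 1.54 ± 0.05, whereas the TFIIIC subunit gene sfc6 had a change of -2.05 ± 0.07. Of 13 Tf2 retrotransposons 5 had enough counts to be tested, and all 5 tested were called higher (median 2.13, camera adjusted p = 0.0267, adjusted p = 0.353 with an estimated correlation), and their near-identical copies can share counts. In all, 1085 genes were called higher and 926 lower.

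At 4 and 8 h with cycloheximide str3 and cta3 were still far above 0 h, and the genes pgk1, eng1, adg1 and dut1 were lower. The log2 fold changes of cta3 were 11.08 ± 0.12 at 4 h and 10.94 ± 0.12 at 8 h, and those of str3 11.53 ± 0.17 and 10.55 ± 0.17. shu1 rose by 10.79 ± 0.21 at 8 h and the dihydroxyacetone kinase gene dak2 by 6.15 ± 0.14 at 4 h. Iron acquisition genes were higher in 12 cases and lower in 1 of 14 at 4 h (median 2.53, camera adjusted p = 7.5e-05, adjusted p = 0.219 with an estimated correlation). At 8 h 12 of them were higher (median 2.54, camera adjusted p = 4.1e-05, adjusted p = 0.248 with an estimated correlation). pgk1 had changes of -6.13 ± 0.15 at 4 h and -6.10 ± 0.15 at 8 h, and the glycolysis list had 4 genes higher and 11 lower at both times. The medians of that list were -1.54 (camera adjusted p = 0.00574, adjusted p = 0.686 with an estimated correlation) and -1.54 (camera adjusted p = 0.00847, adjusted p = 0.613 with an estimated correlation). The septum glucanase gene eng1 had changes of -4.91 ± 0.07 and -4.60 ± 0.06, adg1 of -3.96 ± 0.11 and -4.12 ± 0.11, and the dUTPase gene dut1 of -3.50 ± 0.07 and -3.91 ± 0.07. Of the 32 tested genes of mitosis, septation and cell separation, 10 were called lower and 5 higher at 4 h, with a median of 0.01, a mean of -0.43 and no camera call (camera adjusted p = 0.945, adjusted p = 0.971 with an estimated correlation). At 8 h 11 were lower and 5 higher (median 0.02, mean -0.48, camera adjusted p = 0.961, adjusted p = 0.979 with an estimated correlation). Of the G1/S genes, 7 were called lower and 1 higher at 4 h (median -0.59, camera adjusted p = 0.0119, adjusted p = 0.686 with an estimated correlation). At 8 h, 10 of 22 G1/S genes were called lower and 1 higher (median -0.58, camera adjusted p = 0.00459, adjusted p = 0.500 with an estimated correlation). The lower ones included mik1 (-3.15 ± 0.09), which encodes an inhibitory kinase of Cdc2. Ribosomal protein genes had a median of -0.80 at 8 h, with 13 called lower and 1 higher (camera adjusted p = 4.9e-13, adjusted p = 0.588 with an estimated correlation). The regulators of meiosis and mating mei2 and spk1 rose by 3.41 ± 0.08 and 3.26 ± 0.10 at 8 h, urg1 by 6.68 ± 0.12 and isp5 by 6.43 ± 0.10. tgp1 stood 2.43 ± 0.07 above 0 h at 4 h and 1.57 ± 0.07 at 8 h, pho7 1.65 ± 0.04 and 1.58 ± 0.04, and maf1 1.95 ± 0.06 and 1.75 ± 0.06. pho1 was not called at either time, with log2 fold changes of -0.01 ± 0.08 and -0.52 ± 0.08, and SPNCRNA.1343 rose by 1.52 ± 0.06 and 1.82 ± 0.06. Counts at tRNA genes were higher in 35 of 38 cases at 4 h (median 3.80, at the bound 3.38, camera adjusted p = 3.7e-05, adjusted p = 0.0228 with an estimated correlation). In all, 947 genes were called higher and 948 lower at 4 h, and 808 and 903 at 8 h, or 1100 and 635 with library size alone (median of all genes 0.18 at 8 h).

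**Figure D2:**
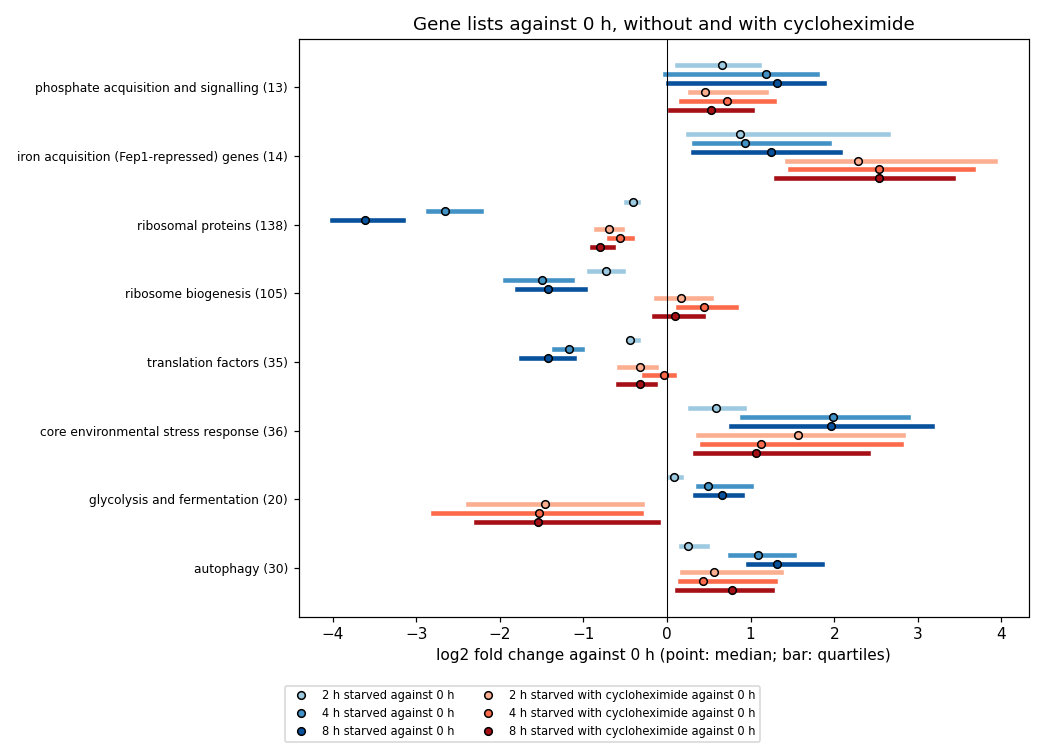
Log2 fold changes against 0 h of 8 gene lists, without drug (blue) and with cycloheximide (red) at 2, 4 and 8 h, the points marking medians and the bars quartiles over the tested members. The median of the ribosomal protein genes was -3.61 at 8 h without drug and -0.80 with it.

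Comparing drug with no drug at the same time keeps the medium and the time of starvation fixed. At 2 h pho1 and tgp1 were lower with cycloheximide, with log2 fold changes of -2.31 ± 0.08 and -1.29 ± 0.06. The genes pqr1, kcs1 and pho7 were higher by 1.97 ± 0.05, 1.16 ± 0.04 and 1.10 ± 0.04. cta3 (8.93 ± 0.10), atf21 (6.56 ± 0.22) and str3 (6.04 ± 0.11) were among the highest. The lowest included urg2 (-7.47 ± 0.13), urg1 (-6.14 ± 0.12), pgk1 (-5.40 ± 0.14) and the alanine racemase gene alr2 (-5.07 ± 0.15). Genes of nitrogen starvation and amino acid permeases went both ways, 3 of 16 higher and 5 lower (median -0.15, camera adjusted p = 0.846, adjusted p = 0.952 with an estimated correlation). Among them were isp5 with -3.20 ± 0.08, put4 with -3.02 ± 0.08 and the ammonium transporter gene amt3 with 3.76 ± 0.11. ecl3 had a change of -3.45 ± 0.18. Ribosome biogenesis genes were higher with drug in 50 of 105 cases and lower in 1 (median 0.95, camera adjusted p = 7.0e-14, adjusted p = 0.495 with an estimated correlation), including rlp7 (2.46 ± 0.04) and gar2 (1.95 ± 0.05). Counts at tRNA genes were higher in 36 of 38 cases, with a median of 4.15 or 4.14 at the bound (camera adjusted p = 1.1e-05, adjusted p = 0.0130 with an estimated correlation). These 38 of 187 genes could pass the filter through the drug libraries. All tRNA genes together had a median of 112 counts per library without and 1499 with drug. The small RNA genes snu4 and snoU14 were higher by 3.42 ± 0.25 and 3.07 ± 0.05. The 5 tested Tf2 retrotransposons were all called higher (median 2.56, camera adjusted p = 0.0177, adjusted p = 0.291 with an estimated correlation). maf1 was higher by 1.21 ± 0.06, and seb1, a factor of 3' end formation by RNA polymerase II, by 1.87 ± 0.03. Respiratory chain and ATP synthase genes were lower in 10 of 48 cases (median -0.66, camera adjusted p = 2.2e-06, adjusted p = 0.291 with an estimated correlation). In all, 1013 genes were called higher and 862 lower.

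At 4 and 8 h the genes of the ribosome were higher with cycloheximide than without, and pho1 and tgp1 were lower. At 4 h, 135 of 138 ribosomal protein genes were called higher (median 2.05, camera adjusted p = 6.7e-24, adjusted p = 0.499 with an estimated correlation). At 8 h 137 were (median 2.82, camera adjusted p = 1.1e-28, adjusted p = 0.626 with an estimated correlation). The changes at 4 and 8 h were 5.72 ± 0.06 and 5.20 ± 0.06 for rpl1603 and 3.89 ± 0.08 and 5.39 ± 0.09 for rpp203. Ribosome biogenesis genes were higher in 91 of 105 cases at 4 h (median 2.01, camera adjusted p = 9.6e-21, adjusted p = 0.404 with an estimated correlation). At 8 h 81 of them were higher (median 1.57, camera adjusted p = 1.1e-17, adjusted p = 0.596 with an estimated correlation), and rlp7 was higher by 3.58 ± 0.04 at 4 h and 3.42 ± 0.04 at 8 h. The tRNA 3' processing gene trz2 was higher by 3.15 ± 0.05 and 2.92 ± 0.05, and the polymerase I factor gene rrn3 by 2.83 ± 0.04 and 2.09 ± 0.04. pho1 had changes of -3.21 ± 0.09 and -4.69 ± 0.09, tgp1 of -3.44 ± 0.06 and -5.38 ± 0.07, and pho84 of -2.05 ± 0.07 at 8 h. SPNCRNA.1343 was higher by 4.50 ± 0.08 at 4 h and 4.69 ± 0.08 at 8 h. Glycolysis and fermentation genes were lower in 15 of 20 cases and higher in 2 at 4 h (median -2.13, camera adjusted p = 3.3e-04, adjusted p = 0.499 with an estimated correlation). At 8 h they were lower in 16 cases and higher in 2 (median -2.41, camera adjusted p = 7.5e-05, adjusted p = 0.626 with an estimated correlation). The change of pgk1 was -7.10 ± 0.16 at 4 h and -6.89 ± 0.16 at 8 h. Core environmental stress genes went both ways, 9 higher and 15 lower of 36 at 4 h (median -0.40, camera adjusted p = 0.291, adjusted p = 0.827 with an estimated correlation). At 8 h 6 were higher and 16 lower (median -0.68, camera adjusted p = 0.0879, adjusted p = 0.753 with an estimated correlation). Of these cta3 was higher by 8.29 ± 0.10 and 8.69 ± 0.10. The changes were -4.13 ± 0.27 and -4.09 ± 0.27 for hsp16 and -4.12 ± 0.13 and -5.12 ± 0.13 for the peroxiredoxin gene pmp20. The pheromone gene mfm1 had changes of -5.63 ± 0.26 and -7.00 ± 0.13 and mfm3 of -5.84 ± 0.14 at 8 h. Autophagy genes were lower in 8 of 30 cases at 8 h (median -0.68, camera adjusted p = 4.8e-05, adjusted p = 0.596 with an estimated correlation), including atg10 (-1.90 ± 0.08). Counts at tRNA genes were higher in 32 cases and lower in 3 at 4 h (median 3.47, at the bound 3.22, camera adjusted p = 0.00406, adjusted p = 0.236 with an estimated correlation). In all, 1272 genes were called higher and 1339 lower at 4 h, where library size alone moves the median of all genes to -0.14. At 8 h they numbered 1093 and 1331.

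**Figure D3:**
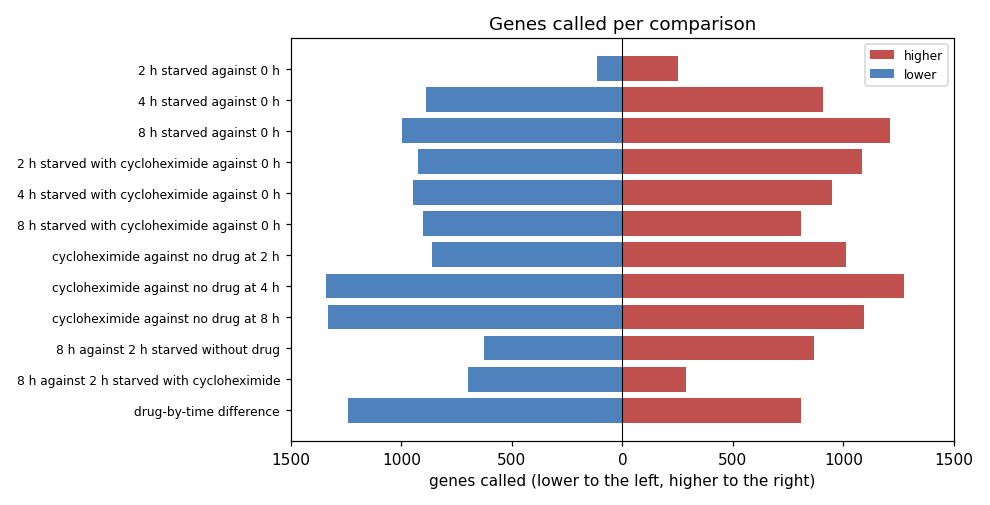
Number of genes called at an adjusted p below 0.05 and a change of at least 2-fold in each of 12 comparisons, with genes called lower drawn to the left of 0 and genes called higher to the right. Without drug the calls against 0 h went from 252 higher and 116 lower at 2 h to 1212 and 997 at 8 h.

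Between 2 and 8 h of starvation without drug, pheromone and stress genes rose and ribosomal protein genes fell. mfm1 rose by 6.60 ± 0.12, mfm3 by 5.36 ± 0.14, fbp1 by 5.03 ± 0.12, gpd3 by 4.46 ± 0.11, zym1 by 5.05 ± 0.16 and hsp16 by 3.68 ± 0.27. M-cell specific genes were called higher in 6 of 7 cases (median 2.38, camera adjusted p = 0.00118, adjusted p = 0.381 with an estimated correlation). tgp1 and pho1 rose by 2.12 ± 0.06 and 2.01 ± 0.08, gde1 by 1.09 ± 0.05 and maf1 by 1.36 ± 0.06, and SPNCRNA.1343 had a change of -1.88 ± 0.09. All 138 ribosomal protein genes were called lower (median -3.18, camera adjusted p = 1.2e-38, adjusted p = 0.381 with an estimated correlation), including rpp203 (-5.78 ± 0.09) and rps1402 (-4.95 ± 0.09). Autophagy genes were higher in 15 of 30 cases (median 1.01, camera adjusted p = 2.2e-10, adjusted p = 0.300 with an estimated correlation). Core environmental stress genes were higher in 20 of 36 (median 1.21, camera adjusted p = 6.4e-06, adjusted p = 0.387 with an estimated correlation). isp5 and ptr2, both for nutrient permeases, had changes of -2.29 ± 0.08 and -1.80 ± 0.08. In all, 869 genes were called higher and 626 lower (median of all genes 0.12 with library size alone).

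With cycloheximide the change from 2 to 8 h took in fewer protein-coding genes, with 182 called higher and 259 lower against 544 and 470 without drug, and 379 noncoding RNA genes were called lower. urg2 (7.10 ± 0.13), urg1 (6.30 ± 0.12), isp5 (5.05 ± 0.08), mfm2 (5.58 ± 0.31), shu1 (3.95 ± 0.11) and spk1 (3.63 ± 0.10) rose. Among the genes that fell were adg1 (-3.60 ± 0.11), agn1 (-3.32 ± 0.09), the replication licensing gene cdc18 (-2.60 ± 0.09) and cdt2 (-2.15 ± 0.10). Of the list of mitosis, septation and cell separation, 7 of 32 genes were called lower (median -0.02, camera adjusted p = 0.598, adjusted p = 0.929 with an estimated correlation). Of the G1/S genes 8 of 22 were lower and 1 higher (median -0.67, camera adjusted p = 0.00903, adjusted p = 0.661 with an estimated correlation). tgp1 changed by -1.97 ± 0.06, amt3 by -3.58 ± 0.11 and the catalase gene ctt1 by -2.47 ± 0.11. Counts at tRNA genes were lower at 8 h than at 2 h in 32 of 38 cases and higher in 3, or 32 and 4 adjusted over the list alone (median -3.19, camera adjusted p = 8.3e-05, adjusted p = 0.0278 with an estimated correlation). Small nuclear and nucleolar RNA genes were lower in 18 of 44 cases (median -0.80, camera adjusted p = 3.0e-04, adjusted p = 0.151 with an estimated correlation). All 5 tested Tf2 retrotransposons were lower (median -2.12, camera adjusted p = 0.00903, adjusted p = 0.217 with an estimated correlation). Noncoding RNA genes were lower in 379 and higher in 100 of 1225 cases (median -0.46, camera adjusted p = 2.4e-05, adjusted p = 0.151 with an estimated correlation). In all, 287 genes were called higher and 700 lower (median of all genes 0.13 with library size alone). With the stricter filter on low counts 456 were lower, 438 of them among the 700, and the other 262 of the 700 were not tested.

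The interaction of drug and time, the change from 2 to 8 h with cycloheximide less that without, tests directly whether the time courses differ. isp5 (7.33 ± 0.11), urg2 (7.08 ± 0.15), urg1 (5.87 ± 0.15), rpp203 (5.50 ± 0.12) and rps1402 (4.89 ± 0.11) had positive values, and all 138 ribosomal protein genes were called higher (median 3.11, camera adjusted p = 4.7e-35, adjusted p = 0.472 with an estimated correlation). mfm3 (-8.63 ± 0.21), the noncoding RNA meu3 (-7.41 ± 0.38), hry1 (-6.28 ± 0.41), gpd3 (-5.65 ± 0.15), zym1 (-4.59 ± 0.21) and ctt1 (-5.01 ± 0.16) had negative values. tgp1 (-4.09 ± 0.08), pho1 (-2.38 ± 0.11), pho84 (-1.51 ± 0.10) and maf1 (-1.68 ± 0.08) were lower and SPNCRNA.1343 (2.72 ± 0.10) higher in this comparison. At 2 h maf1 was at 97.8 to 105 CPM per library with drug and 42.5 to 44.1 without. By 8 h it was at 74.1 to 88.1 with drug and 108 to 118 without. Its negative value thus holds a higher level with drug at 2 h as well as a lower one at 8 h. The positive values of urg1 and urg2 hold their lower level with drug at 2 h, given above. Core environmental stress genes were called lower in 23 of 36 cases (median -1.76, camera adjusted p = 1.1e-05, adjusted p = 0.472 with an estimated correlation). The same held for 16 of 30 autophagy genes (median -1.03, camera adjusted p = 3.0e-08, adjusted p = 0.143 with an estimated correlation). Of the noncoding RNA genes 520 were lower and 134 higher (median -0.78, camera adjusted p = 1.0e-07, adjusted p = 0.0842 with an estimated correlation), or 519 and 133 adjusted over the list alone. In all, 807 genes were called higher and 1240 lower, and 5 of 100 ways of splitting the libraries, the real one among them, gave as many called genes.

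For every other list above, the counts of called members adjusted over the list alone were those given. Of the camera calls given above, those that held at an adjusted p below 0.05 with an estimated correlation were those of the tRNA genes at 2 and 4 h with cycloheximide against 0 h, at 2 h with against without drug, and at 8 against 2 h with drug. Only 38 of 187 tRNA genes were tested, and they could pass the filter through the drug libraries, so these calls depend in part on the filter.

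Starvation calls with and without cycloheximide, each against the same 3 libraries of 0 h, overlapped. At 2, 4 and 8 h, 164, 355 and 453 genes were called higher in both, where independent lists of those sizes would share 42.8, 134 and 153. Genes called lower in both numbered 24, 141 and 203, against 16.8, 132 and 141 for independent lists. With library size alone, 83 and 125 genes were called lower in both at 4 and 8 h, against 82.9 and 77.7 for independent lists, so that the 4 h count was no higher than that of independent lists. Across genes, which are not independent replicates, Pearson's r was 0.378, 0.317 and 0.410 and Spearman's rho 0.328, 0.229 and 0.341, against a Pearson's r of 0.0515, 0.0537 and 0.0576 for 20 simulations of unchanged groups with these controls. The covariance of the log2 fold changes was 0.295, 0.486 and 0.711, against 9.4e-04, 9.8e-04 and 0.00101 in the simulations. The simulated groups were drawn from the mean of the same 3 control libraries, which leaves out the control error that both comparisons share. The simulations therefore give no level for what sharing the controls adds. The 3 controls were too few to split, so part of the overlap, correlation and covariance may come from sharing them. How large that part is was not estimated.

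Genes that starvation moved by 4 h were looked up in the separate libraries of drug against no drug at 8 h. Of the 906 genes called higher at 4 h, 545 (60.2%) were lower with cycloheximide at 8 h, against 20.8% of all tested genes. Of the 889 called lower, 567 (63.8%) were higher, against 17.1%. Genes called at 8 h and looked up at 4 h gave 588 of 1212 (48.5%, against 20.9%) and 614 of 997 (61.6%, against 19.9%).

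By class of RNA, tRNA genes took 2.9e-04% ± 5.1e-05 of counts at 0 h (mean ± SD, n = 3), 4.0e-04% ± 3.7e-05 at 2 h and 0.00106% ± 6.5e-05 at 8 h without drug. Of the 38 tested tRNA genes 9 were called higher and 7 lower at 8 h without drug against 0 h, or 8 and 4 adjusted over the list alone, with no camera call (camera adjusted p = 0.538, adjusted p = 0.606 with an estimated correlation). A camera call of a rise was made there with the libraries of the compared groups only. Their median was -0.14, or 0.83 at the bound, and their mean 0.36. With cycloheximide they took 0.00523% ± 2.5e-04, 0.00339% ± 2.0e-04 and 0.00121% ± 9.8e-05 at 2, 4 and 8 h. These shares rest on few counts, with a median of 78 counts per library at 0 h and 1499 at 2 h with drug. Over the 3 times the share was higher with drug (exact permutation test within times, two-sided, 8000 relabellings of the 18 starved libraries, p = 5.0e-04, adjusted p = 0.00300). Small nuclear and nucleolar RNA genes took 0.0337% ± 6.9e-04 at 2 h without and 0.122% ± 0.00274 with drug, and 0.0462% ± 0.00111 without and 0.0455% ± 0.00102 with drug at 8 h. Over the 3 times together their share was higher with drug (exact permutation p = 0.00400, adjusted p = 0.00600). Noncoding RNA genes took 1.34% ± 0.0170 and 2.32% ± 0.0880 at 2 h, and 1.84% ± 0.139 and 1.82% ± 0.0204 at 8 h (exact permutation p = 0.00275, adjusted p = 0.00550), a call lost without the 10 most abundant genes (adjusted p = 0.0859). Each time alone, with 3 libraries against 3, cannot go below p = 0.10 in an exact test.

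The authors' deposited tables compare the 6 starved groups with 0 h. Only the genes tested here were counted in them. At 8 h without drug the authors' deposited table has 1238 of these genes higher and 967 lower at the same thresholds. Of those, 1212 and 967 were also called here. For 2 h with cycloheximide the authors' deposited table has 1139 and 849 of the tested genes, of which 1082 and 849 were also called here. Over the 6 comparisons the log2 fold changes of the authors' deposited tables and those computed here had a Pearson's r across genes of 0.997 to 1.00.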

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

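The tests of scaling, shared reads, decay, carry-over of RNA without a poly(A) tail, transcription and medium, and the breakdown of the splits by drug label, were chosen only after the results were seen.

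Each value here is of the interaction of drug and time, the change from 2 to 8 h with cycloheximide less that without, in which the edgeR test of the interaction found a difference between the time courses. It called 807 genes higher and 1240 lower. Of the 100 splits drawn from the 200 possible, 5 gave as many called genes as the real split, which called 2047, and the highest other split called 2640, so this test does not exclude chance. The 4 other splits with as many genes are all among the 14 drawn that kept or exchanged the real drug labels at one of the times, and the highest elsewhere was 0. Elsewhere drug and no drug were mixed at both times, which widens the spread within groups, so that 0 is no evidence against chance. Splits that call more genes than the real one point to a structure of the samples, here the difference between drug and no drug. The named genes with positive values, on the log2 scale, were isp5 (7.33), urg2 (7.08), urg1 (5.87), pfd1-antisense-1 (5.57), rpp203 (5.50), rps1402 (4.89) and SPNCRNA.1343 (2.72). Those with negative values were mfm3 (-8.63), ubp16-antisense-1 (-7.43), meu3 (-7.41), hry1 (-6.28), cds1-antisense-1 (-6.18), min8 (-5.98), tgp1 (-4.09), pho1 (-2.38), maf1 (-1.68) and pho84 (-1.51). The values of maf1, urg1 and urg2 hold differences between drug and no drug at 2 h, as given above.

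Lists with a positive median in this interaction, with the adjusted p of an estimated correlation in brackets, were ribosomal proteins at 3.11 (adjusted p = 0.472), translation factors at 1.08 (adjusted p = 0.472), aminoacyl-tRNA synthetases at 0.96 (adjusted p = 0.472), amino acid biosynthesis at 0.72 (adjusted p = 0.472) and purine and pyrimidine biosynthesis at 0.60 (adjusted p = 0.561). Smaller positive medians were those of ribosome biogenesis at 0.55 (adjusted p = 0.472), RNA polymerase I and III machinery at 0.50 (adjusted p = 0.472), proteasome at 0.44 (adjusted p = 0.472), tRNA processing at 0.40 (adjusted p = 0.505) and nonsense-mediated decay and exosome at 0.26 (adjusted p = 0.472). Negative medians were those of core environmental stress genes at -1.76 (adjusted p = 0.472), glucose-repressed and hexose transport genes at -1.28 (adjusted p = 0.472), autophagy at -1.03 (adjusted p = 0.143), histones at -0.71 (adjusted p = 0.472), glycolysis and fermentation at -0.62 (adjusted p = 0.526), phosphate genes at -0.61 (adjusted p = 0.472) and Pap1 genes at -0.52 (adjusted p = 0.505). Among genes of RNAs without a protein, noncoding RNA genes had a median of -0.78 (adjusted p = 0.0842), tRNA genes of -2.91, or -3.03 without those that had a group at 0 (adjusted p = 0.0531), rRNA genes of -2.43 (adjusted p = 0.125) and tested Tf2 retrotransposons of -1.91, or -2.07 without such genes (adjusted p = 0.472).

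Ribosomal protein genes fell at 8 h without drug and far less with cycloheximide, with a median interaction of 3.11. The choice of TMM factors made little difference, with a median at 8 h of -3.61 with them and -3.41 with library size alone. A large shift was not possible, as the factors were 0.90 to 0.93 at 0 h and 1.00 to 1.07 at 8 h. Library size is a relative scale too, so this cannot decide on composition or on the total amount of RNA. Reads shared between paralogous copies are argued against as the whole cause by the 22 genes taken as having 1 copy by symbol. Their median was -3.08 (bootstrap 95% interval -3.31 to -2.85), beside -3.68 (-3.80 to -3.57) for the other 116. The rule on symbols missed the pair rpl35A01 and rpl35A02, which is among the 22. A stop of the decay of all transcripts under cycloheximide is argued against by the abundant genes pgk1 (-5.36), eno101 (-4.60), tdh1 (-4.29), ssa2 (-4.07) and hsp90 (-3.27) at 2 h with drug against 0 h. If even the smallest of these falls, that of hsp90, were only dilution, 3788 of 6392 genes (59.3%) would have had to rise at least 8-fold in amount within 2 h. What stays open is a slower decay of the ribosomal protein transcripts under cycloheximide, which may hold them up when translation stops, and a fall that needs new proteins. Neither was tested.

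Counts at tRNA genes rose with cycloheximide at 2 h by a median log2 fold change of 4.15 against no drug. Reads from neighbouring transcripts that rose as a whole are argued against by the 75 nearest tested genes. Their median was -0.18 (bootstrap 95% interval -0.30 to 0.14), with 8 called higher and 12 lower. Distance and strand were not used. Totals of the neighbours would not show reads past their ends, which could make up counts as few as those of the tRNA genes. That source stays open. Carry-over of RNA without a poly(A) tail that raises all such classes alike is argued against by the tRNA median, which exceeded the pooled median of the 73 rRNA and small nuclear and nucleolar RNA genes (0.94) by 3.21 (2.46 to 3.58, 10000 draws). The filter, which kept 38 of 187 tRNA genes, can widen this gap. Class shares over all genes, which the filter does not touch, were 4.0e-04% without and 0.00523% with drug at 2 h for tRNA genes. They were 0.0337% and 0.122% for small nuclear and nucleolar RNA genes, and 0.00187% and 0.00438% for rRNA genes. A candidate explanation that stays open is polyadenylation of tRNA transcripts that escape processing or decay, which may be tied to the study's question on tRNA production. It was not tested, and a carry-over specific to tRNAs stays open too.

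pho1 and tgp1 rose without drug, and with cycloheximide tgp1 rose less and pho1 was not called. The change of medium and the loss of phosphate cannot be told apart as the source of the rise, because 0 phosphate-replete libraries came from the starvation medium. A loss of transcription of all genes under cycloheximide from 0 h on is argued against by the later course of the 1085 genes called higher at 2 h with drug, str3 (11.99) and tgp1 (3.54) among them. With decay alone from 0 h on, at rates that stay as they are, these would be the slower to decay and would go on rising against the rest, but from 4 to 8 h with drug their median fell by 0.33 (bootstrap 95% interval -0.36 to -0.28) relative to all genes. A loss of transcription that followed an early rise predicts such a fall too, so the test cannot decide on it and it stays open. A need for new protein synthesis in the rise of pho1 stays open and was not tested.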

How the results depend on the processing

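All alternatives were fixed beforehand, and the cause of the changes below was not tested except where given. Of the results on counts of calls, overlap, look-up and class shares, all 37 under RLE, all 24 each under DESeq2, no filter, the compared groups only and the replicate block, and all 4 under any fold in the look-up kept their side of the threshold or stayed within 1.5 times. With library size alone, 30 of 33 did. Genes lower at 2 h against 0 h came to 76, all among the 116, and genes lower both with and without drug came to 83 at 4 h and 125 at 8 h. The stricter filter kept 22 of 24. Genes lower at 2 h came to 77, all among the 116, of which 37 were not tested and 2 tested but not called. Genes lower at 8 against 2 h with drug came to 456, with 438 of the 700 and 18 others, and the remaining 262 were not tested. Without the 10 most abundant genes the difference in share between drug and no drug was -0.349 percentage points for protein-coding (adjusted p = 0.0859), 0.308 for noncoding RNA (adjusted p = 0.0859) and 8.2e-04 for rRNA genes (adjusted p = 0.106), no longer past 0.05. Leaving out 1 library moved no count by over 1.5 times (genes lower at 2 h 105 to 122, genes higher at 8 h 1194 to 1227). The tRNA gene SPATRNASER.02 in 4 h starved against 0 h had a log2 change of -3.71 (adjusted p = 0.0344), and of -4.25 to 0 with 1 library left out. The 0 (adjusted p = 1) came without replicate 3 of 0 h, which left no counts, so it has no direction, and the fitted fold is no bound. Of the list calls, 1 was lost with RLE, 8 with library size alone, 3 with no filter, 3 with the stricter filter, 7 with the compared groups only and 8 over all settings that left out 1 library, among these, in the interaction of drug and time, that of the phosphate list with the compared groups only and that of nonsense-mediated decay and exosome with the stricter filter. Of the named-gene calls, 25 were lost with RLE, 49 with library size alone, 18 with the stricter filter, 23 with the compared groups only, 2 with the block, 28 with DESeq2 and 109 over all settings that left out 1 library. Among these, ppx1 in 4 h starved against 0 h had a log2 change of -0.98 with RLE or DESeq2, -0.81 with library size alone, -0.99 with the stricter filter and -0.98 without replicate 3 of 0 h or replicate 1 of 4 h. For csk1 in 4 h starved against 0 h the changes were -0.98, -0.80 and -0.99, and -0.98 without replicate 3 of 4 h. That of ppx1 in 8 h starved against 0 h was -0.87 with library size alone. All of these kept an adjusted p below 0.05 and fell short of the 2-fold threshold. The labels do not say whether a replicate number marks a shared batch. The 63 pairs of same-numbered libraries correlated at -0.54 to 0.51 (median 0.07, 30 over 0.1), the other 126 at a median of -0.04, and 12 of 21 libraries correlated best with their own number. These values leave a shared batch open. With that number as a block, 1212 genes were called higher at 8 h against 0 h and 862 lower with drug at 2 h, the same counts as without it, and no count of calls moved by over 1.5 times. DESeq2 left the adjusted p of 268 genes per comparison undefined, and camera was not run with it. Depth limits the tRNA genes, with 53 to 1778 counts per library over all of them.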

Other observations

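The gene groups in the next 2 paragraphs were picked after the data were seen, from a scan of 330 product words over 12 word lists and 6 comparisons in which 167 of 3960 tests passed, so that their values are no independent evidence. The tests of antisense RNAs and of other splits were planned before their results were seen.

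Counts at wtf elements, a multigene family that includes meiotic drivers, rose with starvation. Of 25 tested elements, 16 were called higher at 4 h (median log2 fold change 1.07, camera adjusted p = 0.0364 with an estimated correlation) and 21 at 8 h (median 2.02, adjusted p = 0.00511 with an estimated correlation). With cycloheximide 14 were higher at 2 h (median 1.35, adjusted p = 0.00899) and 19 at 8 h (adjusted p = 0.00138). From 2 to 8 h without drug 20 rose (median 1.69, adjusted p = 0.00258), and in the interaction of drug and time 17 were lower (median -1.22, adjusted p = 0.0295). Without drug 0 were called at 2 h against 0 h (median 0.24). With against without drug, 13 were higher and 0 lower at 2 h (median 1.01), and 12 and 0 at 4 h (median 0.84). At 8 h 4 were higher and 3 lower (median 0.18). The negative interaction thus goes with higher counts under drug at 2 h, and not with lower counts under drug at 8 h. These elements share sequence, and their counts are uncertain where reads could be split between them.

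Genes of transmembrane transporters were higher in 29 of 153 cases and lower in 2 at 2 h without drug (median 0.26, adjusted p = 0.00145 with an estimated correlation) and in 55 and 10 at 2 h with cycloheximide (median 0.54, adjusted p = 0.00696). Mitochondrial ribosomal protein genes had a median of -0.41 at 8 h without drug (adjusted p = 0.0697 with an estimated correlation), beside -3.61 for those of cytosolic ribosomes. Of 8 subunits of the cytosolic chaperonin CCT, 5 were called lower at 8 h (median -1.13, adjusted p = 0.193 with an estimated correlation).

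A rise of an antisense RNA may go with a fall of the gene opposite. At 8 h against 0 h, across 488 antisense RNAs and the genes opposite them, Spearman's rho was -0.140 and Pearson's r -0.201 (permutation p = 0.00227, adjusted p = 0.00681, 100000 permutations), across genes, which are not independent replicates. Of the genes opposite the 157 antisense RNAs called higher, 38 were lower and 29 higher, and of those opposite the 70 called lower, 8 were lower and 22 higher. The other 2 comparisons tested gave a rho of -0.0163 for cycloheximide against no drug at 8 h (permutation p = 0.720, adjusted p = 0.720) and 0.0513 for 2 h with cycloheximide against 0 h (permutation p = 0.258, adjusted p = 0.386), so that the relation was seen in 1 of 3, and counting without strand would give such pairs shared counts, which would make them move together.

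The number of genes called by edgeR was set beside other splits of the same 6 libraries for 11 comparisons. With 10 splits each, too few for a share under 0.05, 1 split, the real one, gave as many, and the highest other split called 0 genes in each. The other splits mix the compared groups, which puts the difference between these inside each new group and widens its spread. The 0 calls follow from that and are no evidence against chance. The real splits called 368, 1795 and 2209 genes at 2, 4 and 8 h against 0 h, 2011, 1895 and 1711 with cycloheximide against 0 h, 1875, 2611 and 2424 with against without drug, 1495 at 8 against 2 h without drug and 987 with it.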
